A study of Mus musculus with 4 samples.

How the data were processed

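Pituitaries of female FVB hybrid mice aged 3 to 4 months at the start were compared between 2 groups. Per the labels, 14 of 28 mice received VCD, a chemical that destroys the small follicles of the ovary, at 160 mg/kg per day in sesame oil by intraperitoneal injection for 20 days, and pituitaries were collected on days 133 to 138. Each group had 2 pools of 3 pituitaries, each pool from different mice as the labels state, so that a pool was 1 replicate and cells were not replicates. Cells were captured with 10x Genomics 3′ chemistry and sequenced as short reads.

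The deposited files held, for each pool, raw UMI counts per gene and cell barcode with no normalization. Cell Ranger (versions 7.1 and 3.1.0 are both named), STAR and Seurat appear in the submitters' processing notes with no stated order, and the genome build is mm39 (GRCm39) per the submitters' processing notes. The lowest total of any deposited barcode was 500 UMIs in each pool. Gene symbols and Ensembl identifiers were taken from the files, and no coordinates were used.

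Choices of filters, markers, tests, gene lists and the genes to be named were made before the data were examined. Barcodes with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs were kept. Scrublet was run per pool with an expected doublet rate of 0.04. Its automatic threshold called under 0.5% of barcodes in every pool, so the 4% with the highest doublet scores were left out, which was the fallback written for that case. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen per pool and combined, and 30 principal components, 15 neighbours and Leiden clustering at a resolution of 1 were used without batch integration (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15). Clusters were named from fixed marker genes, so that each class is "like" the cell type whose name it carries. The rule written first, that a cluster with marker genes of 2 endocrine classes at full level among its top 10 genes stays unnamed, was put into effect through further thresholds. A cluster stayed unnamed when fewer than 3 markers were detected, when a second class reached 0.6 of the score of the first, when more than 50% of its cells were called doublets, when another class had more markers among the top genes, or when low UMIs came with no marker there. These further thresholds were set after the clusters were seen, and the shares of the clusters they kept out are given with the results.

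For each class with at least 20 cells in every pool, counts were summed per pool and fitted with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) after TMM normalization and its default filter on low counts. The quasi-likelihood F test compared VCD with control, and p-values were adjusted with the Benjamini-Hochberg method over the genes tested in a class. A gene was counted as changed at an adjusted p under 0.05. Log2 fold changes are VCD over control, and each standard error is the absolute log2 fold change over the square root of F. Differences between VCD effects in 1 class and the mean of the hormone cell classes were tested in edgeR on sums per pool and class with the pool as a term. In that test the residual spread came from class-by-pool combinations, which share mice. Means are given with the SD over 2 pools, and CPM are counts scaled to the total of a pool's class.

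Shares of cells were compared with exact permutation tests (two-sided), for which 2 pools against 2 cannot give a p below 0.33. By chance, a measure separates the 2 groups completely in 33.3% of cases. Cells were thinned to 2000 UMIs, and shallower cells left out, before shares of cells with a UMI of a gene were taken. A share of 0 was given with the upper limit from 3 counts, which covers counting error only. Subclusters of gonadotropes and stem cells were made at a resolution of 0.5 with 15 components, without genes at an unadjusted p under 0.05 between the groups. The hormone genes Gh, Prl, Pomc, Tshb, Cga, Lhb and Fshb were also left out. Gonadotrope subtypes set by their own hormone genes could therefore not form. Dividing cells had at least 2 of 6 division genes detected after thinning.

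There were 24 fixed gene lists, tested per class with camera at its preset correlation of 0.01 on log CPM, adjusted over lists and classes. The lists covered gonadotrope identity, activin and inhibin signalling, the immediate early response, estrogen-responsive genes, steroid receptors, secretory granules, endoplasmic reticulum folding, cytosolic ribosomal proteins, nuclear oxidative phosphorylation, mitochondrially encoded genes, proliferation, stem cell identity, lineage transcription factors, Notch, Wnt and Hippo pathways, epithelial to mesenchymal transition, cytokine response, dissociation and heat shock, interferon response, extracellular matrix, p53 targets, Musashi and Pumilio RNA-binding proteins with the leptin receptor, and hormones of other pituitary cells. Camera with an estimated correlation and fry were run beside it. Both rest on the few residual degrees of freedom of 4 pools in 2 groups and were adjusted over 269 tests. They could hardly pass, so a list that did not is not shown to be unchanged. The list of hormones of other pituitary cells held Gh, Prl, Pomc, Tshb, Cga, Lhb and Fshb, so in gonadotropes it included their own hormones.

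The named genes were, in gonadotropes and in stem cells, the 10 with the smallest p per direction among changed genes whose VCD pools both lay beyond both control pools, filled up to 5 per direction with genes that did not pass. For other classes they were the first 3 per direction and the main hormone, and for each list up to 4 members with the smallest p. Lhb, Fshb, Cga, Gnrhr, Fst, Inhbb, Esr1 and Pgr in gonadotropes, and Sox2, Sox9, Aldh1a2 and Mki67 in stem cells, were named whatever their p. Predicted, mitochondrial and ribosomal genes were counted but not named.

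Alternatives were DESeq2 1.42.0, edgeR with size factors of the RLE kind, no filter on low counts, a replicate block, each pool left out in turn, doublets kept, stricter cells (at least 1000 genes, at least 2000 UMIs, at most 10% mitochondrial), classes from clusters at a resolution of 2, and cells thinned to at most 5000 UMIs. When a pool was left out, the lone pool of its group was assumed to vary like the other group. The main edgeR fit in gonadotropes and stem cells and the test of differences between classes were first run on simulated counts with 200 genes changed by known folds. The alternatives and the fits of other single classes were not simulated. In gonadotropes the main fit called 0% of genes changed 1.5-fold, 21.6% of those changed 2-fold and 91.6% of those changed 4-fold, with 9876, 9955 and 10043 genes in the simulated tables. It also called 0, 2 and 9 unchanged genes. In stem cells it called 12.7%, 64.8% and 97.4%, respectively, and 0, 7 and 5 unchanged genes. The test of differences between classes called 59.0% of genes changed 3-fold in the gonadotropes among 11403 genes, and 5 unchanged genes.

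Total depth was 25233947 and 32168929 UMIs in control pools 1 and 2, and 26932111 and 31556766 UMIs in VCD pools 1 and 2. The median UMIs of kept cells were 4142, 5821, 5262 and 5455, in the same order. Classes of under 20 cells in any pool, including Schwann cells, B cells and neutrophils, were not tested for changed genes.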

Results

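Single-cell RNA sequencing was run on pituitaries of 2 groups of female mice, with 2 pools of 3 pituitaries in each. One group had received VCD, which depletes the ovarian follicles and leads to a state like menopause, and the other had received the vehicle. The files held 5248 and 4459 barcodes for control pools 1 and 2, and 4453 and 4817 for VCD pools 1 and 2. After filters, 3891, 3230, 3143 and 3735 cells were kept, in the same order. The median number of genes per kept cell was 1750, 2262, 2215 and 2228.

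The first comparison asked whether ovarian failure changed which cells the pituitary holds. Gonadotropes, the cells that make the gonadotropins LH and FSH, took a larger share of cells in both VCD pools than in either control pool. Lactotropes, the prolactin cells, were the most abundant class in every pool, and stem cells, marked by Sox2 and Sox9, were a smaller class. Gonadotropes were 2.26% (88 cells) and 1.92% (62 cells) of cells in the control pools, and 5.19% (163 cells) and 3.43% (128 cells) in the VCD pools. The mean was 2.09% ± 0.24 (SD, n = 2) against 4.31% ± 1.2 (SD, n = 2), a difference of 2.22 percentage points and 2.06-fold, larger than the spread between pools (exact permutation test, two-sided, p = 0.33). The share without VCD pool 1 was higher by 0.71 on the log2 scale, and without VCD pool 2 by 1.31. Fitted to cell numbers with edgeR's quasi-likelihood test, the log2 difference was 1.02 with an SE of 0.19 and an adjusted p of 0.000129. That fit shared its estimate of spread over all cell classes. Its p-values thus do not rest on the spread of a class's own share between pools alone. Stem cells were 7.68% and 7.46% of control pools and 9.32% and 8.19% of VCD pools, a log2 difference of 0.21 (exact permutation p = 0.33; adjusted p = 0.351 in edgeR on cell numbers). Lactotropes were 50.2% and 47.2% of control pools and 45.5% and 46.0% of VCD pools. Of the 5 lactotrope clusters, 3 separated the groups: the cluster led by Kcnk10 and Creb3l1 held 2.65% and 3.99% of control cells against 9.16% and 15.2% of VCD cells, another 10.1% and 17.1% against 5.35% and 7.1%, and the smallest 0.925% and 1.70% against 3.02% and 2.30%. The others did not, and in the largest control pool 1 stood apart, with 24.0% and 11.9% against 12.2% and 11.6%. These clusters were made with all variable genes. Kcnk10 and Homer1, top genes of the first, were themselves called higher in lactotropes after VCD. The cluster sizes were thus not set apart from changes of genes within lactotropes. Corticotropes were 2.44% and 2.38% of control cells and 3.18% and 2.95% of VCD cells (adjusted p = 0.351 in edgeR on cell numbers). Schwann cells were rare, with 13 and 12 cells in control pools and 2 and 5 in VCD pools (edgeR log2 difference -1.75, adjusted p = 0.0845). Clusters left unnamed held 12.4% and 12.9% of control cells and 9.74% and 11.6% of VCD cells. Of these, a cluster with somatotrope and lactotrope markers held 6.53% and 6.75% against 5.03% and 6.75%, and one with stem cell and lactotrope markers held 4.91% and 4.49% against 2.51% and 3.40%. Smaller unnamed clusters held 0.514% and 1.21% against 1.18% and 0.910% (low UMIs), 0.206% and 0.217% against 0.509% and 0.348% (erythroid and lactotrope markers), and 0.283% and 0.248% against 0.509% and 0.241% (mostly called doublets).

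**Figure D1:**
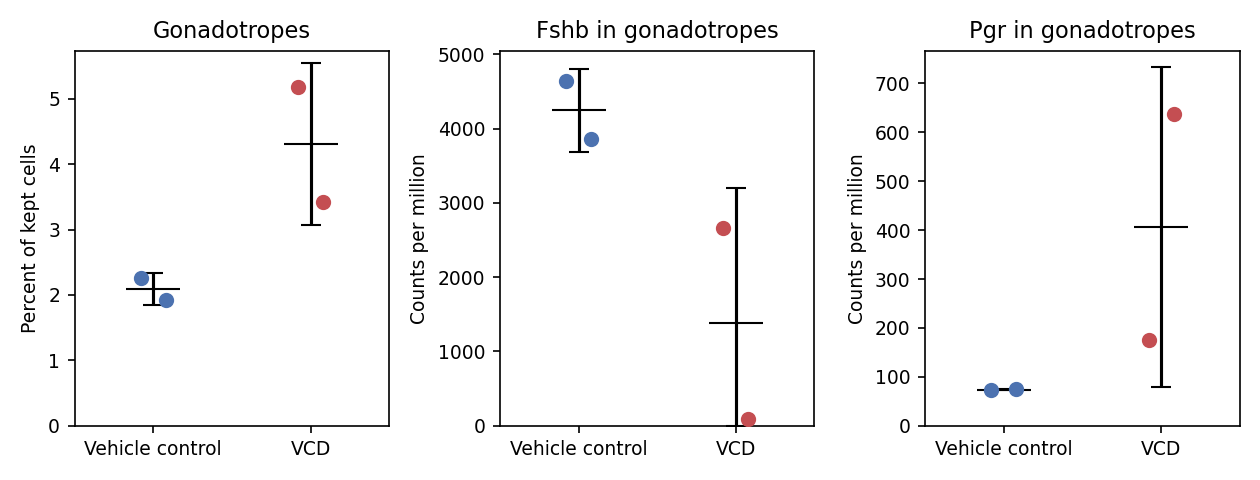
Share of gonadotropes among kept cells in percent (left), and Fshb (middle) and Pgr (right) in gonadotropes in CPM, with 1 point per pool, horizontal lines at the means and bars for the SD (n = 2), which stop at 0. Fshb was 95.0 CPM in VCD pool 2 and 2664 in VCD pool 1.

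Gonadotropes were then compared between VCD and control, because the loss of ovarian steroids removes their feedback. Vip, which encodes vasoactive intestinal peptide, and Slc18a2, which encodes the vesicular monoamine transporter, fell after VCD, as did the cell adhesion genes Cntnap4 and Cntn3. Npas4, a transcription factor gene switched on by electrical activity, rose, together with Dlgap1, which encodes a scaffold protein of synapses. Pgr, the progesterone receptor gene, rose, and Inhbb, which encodes a subunit of activin B and inhibin B, fell. In all, 245 of 9945 genes changed, 139 up and 106 down, and 1537 genes had an unadjusted p under 0.05. Few genes were called without either control pool. The spread then came from the VCD pools alone, so the fall does not show that the calls rested on a control pool. Of the 245 genes, all 242 still measured without control pool 1 kept their direction, as did all 239 without control pool 2. The genes had been chosen with the same pools, so a kept direction was largely fixed in advance and does not test the calls. Without VCD pool 1, 931 were called, of which 234 were among the 245. Of the named genes, Vip, Slc18a2, Cntnap4 and Phactr1 were called with any pool left out, and the others that passed lost their call without either control pool, with the same direction.

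Vip (ENSMUSG00000019772) had a log2 fold change of -4.78 (SE 0.31, adjusted p = 0.000299), from 234 ± 63.4 to 8.55 ± 0.311 CPM. Slc18a2 changed by -3.95 (SE 0.26, adjusted p = 0.000299), from 299 ± 76.7 to 19.5 ± 3.96 CPM. Phactr1, a regulator of actin, changed by -2.57 (SE 0.19, adjusted p = 0.000482), from 1389 ± 321 to 239 ± 22.5. The other genes that fell with the smallest p were Cntnap4 (-5.27), Colec12 (-2.53), Phex (-2.85), Cntn3 (-4.27), Serpinb1a (-3.33), Rbfox1 (-1.48) and Kif26b (-3.08), with adjusted p-values of 0.00664 or lower. Npas4 (ENSMUSG00000045903) rose by 2.48 (SE 0.26, adjusted p = 0.00408), from 23.9 ± 4.59 to 136 ± 15.4 CPM. Hs6st3, a heparan sulfate enzyme gene, rose by 2.10 (SE 0.22, adjusted p = 0.00408), and Dlgap1 by 1.21 (SE 0.15, adjusted p = 0.00716). Tacc2 (1.85), Pcdh7 (1.46), Ephb1 (3.04), Vcan (2.68), Elavl3 (2.87) and Lsmem1 (2.38) rose with adjusted p-values of 0.0081 or lower.

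Among the hormone and receptor genes fixed in advance, Pgr (ENSMUSG00000031870) rose by 2.43 (SE 0.52, adjusted p = 0.0479), with 73.1 and 74.5 CPM in the control pools and 175 and 638 in the VCD pools. The log2 fold change of Pgr was 1.20 without VCD pool 2, and its adjusted p was 0.443 without control pool 1, 0.424 without control pool 2, 0.196 with DESeq2 and 0.0516 with RLE factors. Inhbb changed by -1.65 (SE 0.31, adjusted p = 0.0307). Fshb (ENSMUSG00000027120), which encodes the FSH beta subunit, had 4645 and 3855 CPM in the control pools but 2664 and 95.0 in VCD pools 1 and 2, and a log2 difference of -1.67 did not pass (SE 0.96, adjusted p = 0.461). Cga, the common alpha subunit gene, differed by -0.41 (adjusted p = 0.156), Gnrhr by 0.10 (adjusted p = 0.81) and Esr1 by 0.63 (adjusted p = 0.0739). Fst had 0 UMIs in gonadotropes of all 4 pools and was not tested. Lhb had 434 UMIs in all barcodes together, under 2 gene identifiers that share its symbol (ENSMUSG00000100916 with 432 UMIs and ENSMUSG00000118462 with 2). Gonadotropes held 340 of them. Why so few were counted was not tested. Its level, with a log2 difference of 0.22 (edgeR adjusted p = 0.76), was therefore not read as that of the LH beta transcript.

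Fixed gene lists were tested in gonadotropes with camera, and no list passed with an estimated correlation (each adjusted p at least 0.954). Immediate early genes, which respond to GnRH within minutes, were higher (adjusted p = 0.0272, adjusted p = 0.954 with an estimated correlation), with Atf3 up by 1.05 (edgeR adjusted p = 0.0171). In that list 1 of 14 genes rose, and 5 rose when adjusted over the list alone, with log2 differences of 0.76 for Nr4a3, 0.96 for Klf4 and 0.57 for Dusp1. Cytosolic ribosomal protein genes were lower (80 genes, median log2 difference -0.22, adjusted p = 0.00378, adjusted p = 0.954 with an estimated correlation), with no gene passing singly or when adjusted over the list alone. In the secretory granule list Scg2, which encodes secretogranin II, fell by 1.37 (edgeR adjusted p = 0.0114), and Cpe differed by 0.73 (adjusted p = 0.0646), with a camera adjusted p of 0.844 and 1 gene up and 1 down when adjusted over the list alone. In the Notch list Dlk1 fell by 1.13 and Jag2 by 1.85, both also when adjusted over the list alone (camera adjusted p = 0.0582). Jag2 did not pass with DESeq2 (adjusted p = 0.248). Among lineage transcription factors Neurod4 rose by 2.74 (adjusted p = 0.0384), or 1.78 without VCD pool 2, with 3 genes up and 1 down when adjusted over the list alone (camera adjusted p = 0.334). Nfkbia rose by 1.24 in the cytokine list (3 up and 1 down over the list alone, camera adjusted p = 0.185), Timp1 fell by 1.58 in the matrix list (1 down, 0.0536; adjusted p = 0.226 with DESeq2 for the gene) and Sel1l fell by 1.21 in the endoplasmic reticulum list (1 down, 0.551).

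In the estrogen-responsive list, Pgr alone rose at the genome-wide threshold, while 2 genes rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.526). Rab31 differed by 1.71 (adjusted p = 0.0581) and Gal, which encodes galanin, by -0.81 (adjusted p = 0.0892). Of 5 steroid receptor genes 1 rose, and 3 rose when adjusted over the list alone (camera adjusted p = 0.233). In the gonadotrope identity list 1 gene rose when adjusted over the list alone (camera adjusted p = 0.799), with log2 differences of 0.79 for Nr5a1 and 0.89 for Foxl2, whose adjusted p-values were 0.0906 and 0.188. In the activin and inhibin list 1 gene, Inhbb, fell over the list alone (0.880). The list of hormones of other cells, which also holds the gonadotropes' own Cga, Lhb and Fshb, had 3 genes lower over the list alone (0.119). Wnt genes had 1 lower (0.856). In the remaining lists 0 genes passed in edgeR, also when adjusted over the list alone, with camera adjusted p-values of 0.786 for nuclear oxidative phosphorylation, 0.913 for mitochondrially encoded genes, 0.729 for stem cell identity, 0.295 for Hippo targets, 0.855 for epithelial to mesenchymal transition, 0.799 for dissociation and heat shock, 0.911 for interferon, 0.255 for p53 targets and 0.365 for Musashi and Pumilio. The median and the test had opposite signs in the activin, epithelial to mesenchymal transition and interferon lists. Proliferation genes were too sparse in gonadotropes to be tested as a list.

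Cells were next sorted by Fshb and by the few UMIs counted for Lhb. Because the low Lhb count was not explained, the groups with and without Lhb are not taken as subtypes by LH. Nearly every control gonadotrope held Fshb, and fewer did in the VCD pools, with a wide gap between the pair of VCD pools. Cells with Pgr were more frequent in VCD pool 2 than elsewhere. After thinning to 2000 UMIs, Fshb was present in 100% (64 of 64) and 95.8% of control gonadotropes, and in 68.6% and 10.0% of those in VCD pools 1 and 2. The difference was -58.6 percentage points (exact permutation p = 0.33), and -29.3 without VCD pool 2 and -87.9 without VCD pool 1. Thinning left out 24, 14, 42 and 28 gonadotropes, and unthinned shares were 95.5%, 95.2%, 74.8% and 22.7%. Before thinning, the gonadotropes of at least 2000 UMIs had a median depth of 5772.5, 10939.5, 10111 and 9676 UMIs. In somatotropes, which should lack Fshb, the background was 2.16%, 2.46%, 1.69% and 0% (which allows up to 1.96%). Thinning left out 57, 47, 15 and 47 somatotropes, and those of at least 2000 UMIs had a median depth of 4645, 6179.5, 7697.5 and 7476 UMIs before it. Fshb without Lhb was found in 90.6%, 81.2%, 53.7% and 7.0% of gonadotropes (difference -55.6 points, -32.2 without VCD pool 2, exact permutation p = 0.33). Fshb with Lhb was found in 9.38%, 14.6%, 14.9% and 3.0% (difference -3.04, exact permutation p = 1), and this difference was 2.90 without VCD pool 2, -8.98 without VCD pool 1, -5.65 without control pool 1 and -0.44 without control pool 2. Lhb without Fshb was found in 0 cells of the control pools, which allows up to 4.69% and 6.25%, and in 3.31% and 12.0% of VCD cells (difference 7.65, exact permutation p = 0.33; 12.0 without VCD pool 1 and 3.31 without VCD pool 2). Neither transcript was seen in 0% (up to 4.69%), 4.17%, 28.1% and 78.0% (difference 51.0, exact permutation p = 0.33; 75.9 without VCD pool 1 and 26 without VCD pool 2). Pgr was present in 10.9%, 12.5%, 24.0% and 65.0% of gonadotropes (unthinned 26.1%, 40.3%, 42.3% and 80.5%), against 1.44%, 4.92%, 4.24% and 9.15% of somatotropes.

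Gonadotropes were also split into subclusters, since the study concerns subtypes of these cells. The 1537 genes at an unadjusted edgeR p under 0.05 were left out, as were the pituitary hormone genes, Fshb, Lhb and Cga among them. In this split 5 subclusters formed, of which 1 separated the groups. Chance alone gives 33.3%. A shift carried by the genes left out could not appear in this split, so it does not show that subtypes kept their shares. The subcluster led by Zfp36l1, Plat, Rbpms and Cyp2f2 held 9.09% and 9.68% of control gonadotropes and 6.75% and 6.25% of those after VCD (exact permutation p = 0.33), with 33 cells in all. Rbpms and Cyp2f2 are stem cell markers, Plat led stem cell clusters, and no gonadotrope marker was among its top 10 genes, so its cells carried stem cell transcripts and it is not counted as a gonadotrope subtype. Another subcluster, of 27 cells with a median of 20690 UMIs, had Crhbp, Angpt1 and Col1a2 among its top genes. These also led a lactotrope cluster, so its cells carried lactotrope transcripts and it is not counted either. Clustered with all variable genes, 4 of 5 separated, one of them led by Chst9, Tacr1, Piezo2 and Pgr with at most 1.61% of the gonadotropes of a control pool and 21.5% and 72.7% of those of the VCD pools; those shares follow from the genes that changed.

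Stem cells were compared because their activation is a subject of the study. Il6 and Cxcl10, genes of secreted inflammatory signals, rose after VCD, as did Serpina3n, a protease inhibitor gene of the acute-phase response. Id1 and Id2, which encode inhibitors of differentiation driven by BMP signals, fell. The stem cell genes Sox2 and Sox9 differed little, and cells in division were rare in every pool. In all, 8 of 11874 genes changed, 4 in each direction, with 903 at an unadjusted p under 0.05. Leaving out control pool 1, control pool 2, VCD pool 1 or VCD pool 2 gave 221, 101, 151 and 53 genes, and all 8 remained each time. Other settings kept fewer: 5 of the 8 with stricter cells, 4 at a resolution of 2, and 0 when cells were thinned to 5000 UMIs (819 at an unadjusted p under 0.05). With DESeq2, 3 of the 8 were called (Id1, Cga and Id2), while its filter on low counts left Cxcl10, Hbb-bt, Il6, Serpina3n and Slc35f4 without an adjusted p. All 8 kept their direction in these settings, which use the same pools that the genes were chosen from. Id1 changed by -1.14 (SE 0.15, adjusted p = 0.00755), from 360 ± 26 to 164 ± 35.3 CPM, Slc35f4 by -1.67 (SE 0.22, adjusted p = 0.00755) and Id2 by -0.84 (SE 0.14, adjusted p = 0.034). Cxcl10 rose by 3.14 (SE 0.48, adjusted p = 0.0267), Il6 by 1.33 (SE 0.21, adjusted p = 0.0286) and Serpina3n by 1.27 (SE 0.22, adjusted p = 0.048, and 0.0508 with RLE factors). Transcripts of other cells were also among the 8: the hemoglobin gene Hbb-bt rose by 2.06 (adjusted p = 0.0267) and the hormone gene Cga fell by 1.06 (adjusted p = 0.0331). Slc35f4 was also a top gene of the gonadotrope subcluster with lactotrope transcripts, so its fall was not set apart from fewer transcripts of other cells. Cdkn1a differed by 1.01 (adjusted p = 0.0642) and Fshb by -2.79 (adjusted p = 0.0608), and neither passed. Sox2 differed by 0.02 (adjusted p = 0.993), Sox9 by 0.19 (adjusted p = 0.796) and Aldh1a2 by 0.02 (adjusted p = 0.991). Mki67 had 7, 0, 4 and 2 UMIs and was not tested.

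In stem cells the interferon and antigen presentation list was higher, with all 15 genes positive and a median log2 difference of 0.50 (camera adjusted p = 3.1e-05, adjusted p = 0.954 with an estimated correlation). No member passed genome-wide in edgeR, and 2 rose when adjusted over the list alone, with differences of 1.02 for H2-Ab1 and 0.56 for Stat2. The cytokine list had Il6 as its gene that rose, also when adjusted over the list alone (camera adjusted p = 0.0536). Dissociation and heat shock genes were higher (adjusted p = 0.00386, adjusted p = 0.954 with an estimated correlation), with 2 genes up when adjusted over the list alone and differences of 0.90 for Hspa1a and 0.61 for Hsph1. Cytosolic ribosomal (0.00177, 18 genes up when adjusted over the list alone), nuclear oxidative phosphorylation (0.00535, 0 genes) and endoplasmic reticulum folding (0.0074, 0 genes) were also higher, each with an adjusted p = 0.954 with an estimated correlation. The gonadotrope identity list was lower (0.0288, adjusted p = 0.954 with an estimated correlation), with 2 genes lower over the list alone, one of them Cga. Stem cell identity (0.389), Notch (0.163), Wnt (0.236), Hippo (0.295), activin and inhibin (0.579), proliferation (0.955), lineage factors (0.707), matrix (0.824), and Musashi and Pumilio (0.955) did not pass, and 0 of their genes did in edgeR, also when adjusted over the list alone. Log2 differences in these lists were -0.45 for Hey1 and -0.55 for Heyl. Over the list alone, 3 immediate early genes were higher and 1 lower (camera adjusted p = 0.185), with 0.70 for Egr2 and 0.57 for Klf4. The other lists gave 1 gene lower for estrogen-responsive genes (0.681) and 1 lower for steroid receptors (0.163), 3 higher for secretory granules (0.799), with 2.09 for Pcsk1 and 2.15 for Pcsk2, 3 higher for mitochondrially encoded genes (0.557), 1 higher for epithelial to mesenchymal transition (0.309), with 0.43 for Cdh1, 2 higher for p53 targets (0.193), and 1 higher and 4 lower for hormones of other cells (0.225). The median and the test had opposite signs for the secretory, mitochondrially encoded, proliferation, matrix, and Musashi and Pumilio lists.

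**Figure D2:**
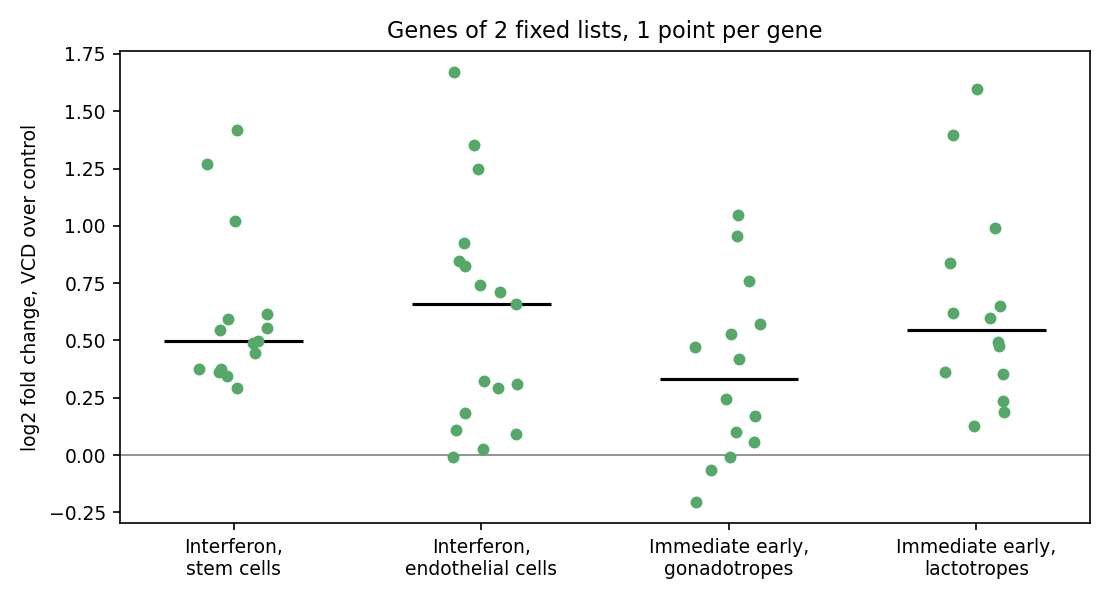
Log2 fold change of VCD over control for each measured gene of the interferon list in stem cells and endothelial cells and of the immediate early list in gonadotropes and lactotropes. Each point is 1 gene, and lines mark the medians. All 15 interferon genes in stem cells lie above 0.

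Dividing cells were rare in all pools. After thinning, 4 of 2979, 4 of 2638, 6 of 2520 and 5 of 3036 cells carried at least 2 of 6 division genes, or 0.134%, 0.152%, 0.238% and 0.165% (exact permutation p = 0.33), a difference of 0.0584 points that was 0.0217 without VCD pool 1 and 0.0951 without VCD pool 2. Among stem cells 1 of 220 cells did in control pool 1 and 0 cells in the other pools, which allows up to 1.79%, 1.37% and 1.33%. Over all cells both VCD pools were above both control pools, but by less than the width of the intervals of the single pools, so a difference was not detectable at this depth, and the exact test of 2 against 2 pools cannot give a p under 0.33 at any depth. Stem cells formed 5 subclusters, 1 of which separated the groups, with 57.5% and 54.4% of control stem cells and 57.7% and 60.1% after VCD (exact permutation p = 0.33). The 903 genes at an unadjusted edgeR p under 0.05 were left out, so a shift carried by them could not appear. Another subcluster, of 99 cells with a median of 15365 UMIs, had Crhbp, Gucy2f and Sgcz among its top genes. These also led lactotrope clusters, so its cells carried lactotrope transcripts.

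Of the other classes, endothelial cells had the most changed genes with all pools in edgeR (106, against 35 in lactotropes), but not without VCD pool 1 (288 against 1274) or VCD pool 2 (126 against 465), and with DESeq2 both classes had 76. Interferon-inducible genes rose in them, including Ifit1, Ifit2 and Gbp6, together with Cd274, which encodes the immune checkpoint ligand PD-L1. Socs3 and Stat3, of the cytokine pathway, rose too, while Mgp, which encodes a matrix protein of vessels, fell. In endothelial cells 106 of 9757 genes changed, 94 up and 12 down, with 288 genes without VCD pool 1 and 69 without control pool 2. Gbp6 rose by 1.91, Cd274 by 1.71 and Samsn1 by 1.30, and Nebl changed by -1.77 (each with adjusted p = 0.00111). Mgp changed by -1.34 (adjusted p = 0.00177) and Igfbp3 by -0.72 (adjusted p = 0.00898). The interferon list was higher (adjusted p = 2.5e-06, adjusted p = 0.954 with an estimated correlation), and 5 of 17 genes rose, or 8 when adjusted over the list alone. Ifit1 rose by 1.67, Ifit2 by 1.25, Ifit3 by 1.35 and Isg15 by 0.85. In the cytokine list (adjusted p = 0.00123, adjusted p = 0.954 with an estimated correlation) 3 of 9 rose, and 5 over the list alone, with Socs3 up by 0.86, Stat3 by 0.78 and Cxcl1 by 1.40. These single calls were less firm: Isg15 (adjusted p = 0.0974 with DESeq2) lost its call without control pool 1, control pool 2 or VCD pool 2 (adjusted p = 0.0982, 0.109 and 0.0609), Stat3 without control pool 1 (0.121), Socs3 without control pool 2 (0.304), and Cxcl1 without control pool 2 (0.263) or VCD pool 2 (0.346, log2 fold change 0.93).

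Klf4, a transcription factor gene, and Atf3, a stress-response gene, rose in lactotropes and somatotropes, and Homer1 and the potassium channel gene Kcnk10 rose in lactotropes. Klf4 and Atf3 did not pass in corticotropes, melanotropes or thyrotropes. Atf3 log2 differences were 0.63 to 0.99 over the hormone classes outside gonadotropes in which it was tested. A class where Atf3 did not pass is thus not shown to lack its rise. The main hormone genes of these classes did not pass. In lactotropes 35 of 14715 genes changed, 19 up and 16 down, but 8 without control pool 2, 21 without control pool 1, 1274 without VCD pool 1 and 465 without VCD pool 2, and 10 with cells thinned to 5000 UMIs. Klf4 rose by 1.60 (adjusted p = 0.0157), Homer1 by 1.28 and Kcnk10 by 1.72, and Prrg1 changed by -1.82, Adgrb3 by -0.99 and Tenm3 by -1.60. Without control pool 2, Klf4 and Homer1 had an adjusted p of 0.0564 each and Adgrb3 of 0.0945, and without control pool 1 Homer1 had 0.058 and Adgrb3 0.0553. These genes lie in cells whose clusters differed in size between the groups. Pcsk1, a prohormone convertase gene, rose by 1.00 (adjusted p = 0.0176) and Tnfaip3 by 1.31 (adjusted p = 0.0383), but Pcsk1 lost its call without control pool 1 (0.0553) or control pool 2 (0.232), while Prl differed by -0.39 (adjusted p = 0.938). The immediate early list was higher in lactotropes (camera adjusted p = 6.4e-11, adjusted p = 0.954 with an estimated correlation), with 3 of 14 genes up and 10 over the list alone. In somatotropes 23 of 9156 genes changed, 14 up and 9 down, but 94 without control pool 1, 48 without control pool 2, 70 without VCD pool 1 and 74 without VCD pool 2. With DESeq2, 12 somatotrope genes were called, and with the replicate block edgeR called 2. All of these were higher, so no lower gene kept its call in either setting. With cells thinned to 5000 UMIs edgeR called 0 (580 at an unadjusted p under 0.05). Klf4 rose by 1.42, Atf3 by 0.92 and Mt2 by 0.88, while Eya1 changed by -1.42, Gpr149 by -2.73 and Prl, another cell's hormone, by -1.31. Gpr149 lost its call without control pool 1 (adjusted p = 0.167) or control pool 2 (0.126), and Prl without VCD pool 1 (0.197) and with DESeq2 (0.125). Gh differed by -0.13 (adjusted p = 0.935).

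Corticotropes had 3 changed genes of 9391: Tacc2 (1.59) and Kcnk10 (3.02) rose and Csmd3 fell by 2.16 (each adjusted p = 0.0448; 0.0504 for Csmd3 with DESeq2), with 24 to 84 genes when a pool was left out, and Pomc differed by -0.19 (adjusted p = 0.90). In macrophages 7 of 6937 genes rose, led by the inflammatory caspase gene Casp4 (1.34, adjusted p = 0.0013), Klf2 (0.98) and Atf3 (0.81), with 20 to 39 genes when a pool was left out, 2 with DESeq2, 2 with doublets kept, 1 with stricter cells and 1 at a resolution of 2. Casp4 had an adjusted p of 0.114 with DESeq2, Klf2 did not pass with DESeq2 (adjusted p = 1.00), without control pool 1 (0.0649) or without VCD pool 1 (0.0894, log2 fold change 0.65), and Atf3 and Jun did not without control pool 1 (0.0676 and 0.0551). Jun rose by 0.76, and the immediate early list was higher (camera adjusted p = 3.05e-05, adjusted p = 0.954 with an estimated correlation), with 3 of 13 genes up and 9 over the list alone. In fibroblasts 1 gene of 3823 rose, Gh, another cell's hormone, with 472 and 491 CPM in control pools and 14409 and 6869 in VCD pools. With doublets kept, 0 fibroblast genes were called. With edgeR, 0 genes changed in melanotropes (497 at an unadjusted p under 0.05, 1 with DESeq2), thyrotropes (473, 1 with DESeq2), pituicytes (152, 0 with DESeq2) and T or NK cells (150, 0 with DESeq2), and leaving out a pool gave between 0 and 78 in these classes. Pomc in melanotropes differed by 0.34 (adjusted p = 0.889) and Tshb in thyrotropes by 1.94 (adjusted p = 0.309), with 353, 1483, 1864 and 5324 CPM. Summed over all cells, 53 of 18630 genes changed, 36 up and 17 down, with 1082 genes without VCD pool 1 and 515 without VCD pool 2. Over all classes, 44 of 269 list tests passed with camera, 41 of them upward, and 0 did with an estimated correlation or with fry, whose smallest adjusted p was 0.378. With 2 pools per group, fry and the estimated correlation could hardly let a list pass, so their results decide nothing about single lists.

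**Figure D3:**
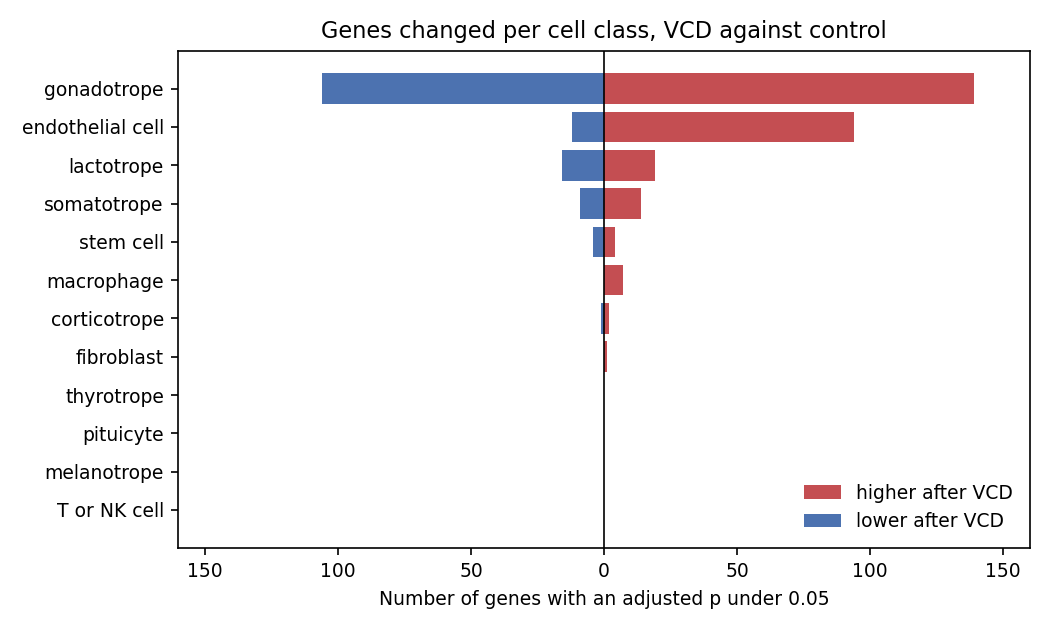
Number of genes with an adjusted p under 0.05 in edgeR per cell class, higher after VCD to the right and lower to the left. Gonadotropes had 139 higher and 106 lower, and endothelial cells 94 higher and 12 lower.

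Whether the VCD effect in gonadotropes was different from that in other hormone cells was tested directly, since free RNA or a library difference acts on every class of a pool. Pgr and Neurod4 rose more in gonadotropes, and Phactr1 and Scg2 fell more. The differences for Atf3 and Fshb did not pass. In all, the effect differed for 344 of 11446 genes, 185 higher and 159 lower, 130 of them among the 245 genes changed in gonadotropes. Without control pools 1 and 2 in turn there were 74 and 60 genes, without VCD pool 1 591, and without VCD pool 2 211. The difference was 2.26 for Pgr, 3.11 for Neurod4, -2.42 for Phactr1 and -1.34 for Scg2. For Atf3 it was 0.23 (adjusted p = 0.762). For Fshb it was -0.01 (adjusted p = 1), with effects of -2.74 to -0.94 in the other hormone classes tested, where few UMIs were counted (79, 66, 70 and 5 in all lactotropes, against 2734, 2795, 3949 and 114 in gonadotropes), so this test did not set Fshb apart from free RNA or a library difference. The counts argued against free RNA as the source of the fall in gonadotropes. In control pools 1 and 2, the 79 and 66 UMIs came from 1955 and 1526 lactotropes, and the 2734 and 2795 from 88 and 62 gonadotropes. A library difference stayed open. In stem cells 0 of 12767 genes differed from the hormone cells in edgeR (532 at an unadjusted p under 0.05; 0 and 531 with RLE factors), with 1, 0, 6 and 1 without control pool 1, control pool 2, VCD pool 1 and VCD pool 2.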

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

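The tests of poor capture, of mice that differ within a pool, of a stem cell joined with a hormone cell of any class, of free RNA and of a harsher dissociation, over all classes and over those with Atf3 called, were chosen after the results were seen. A first free RNA test, of equal added CPM in all classes, was dropped as the depth of cells differs between classes, and the genes, classes and bounds of the test that replaced it were set with their values known. The test of the difference between cell classes found 344 genes whose VCD effect in gonadotropes was not that of the other hormone cells. Among them, Ntm and Lsamp, which encode related adhesion proteins of neurons, had log2 differences of 2.96 and 2.25, and Pip5k1b, a lipid kinase gene, had 2.08. Phactr1 had -2.42, Tshz2, a transcription factor gene, -1.61, and Ccnd2, which encodes cyclin D2, -1.48. Pgr had 2.26, with an effect in other hormone classes of -0.40 to 0.98. Ntm, Lsamp, Pip5k1b, Tshz2 and Ccnd2 were chosen after their values were seen, as the first of the list by p. The spread in this test came from class-by-pool combinations, which share mice.

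Fshb was nearly lost from the gonadotropes of VCD pool 2 and from part of those of VCD pool 1. The other gonadotrope markers in VCD pool 2 had a median log2 ratio to the remaining pools of 0.072 (5 genes, -0.33 to 1.09). Fshb had -5.28. These values argued against poor capture in the cells classed as gonadotropes. The markers also served to name the class, so cells that lacked them may be missing from it. A pool that was not a VCD pool was argued against by the 200 genes farthest apart between VCD 1 and control 1, of which 89.0% (178) differed in the same direction between VCD 2 and control 2, against 60.9% over all genes. Loss of Fshb reads in 1 library would lower Fshb in every class, as less free RNA would (-2.74 to -0.94 in other hormone classes, -1.67 in gonadotropes). It was argued against as the only source within VCD pool 1. There, 78.1% (143 of 183) of the genes higher in VCD pool 2 were also higher in the 38 gonadotropes without Fshb than in the 83 with it. Pgr was present in 39.5% of those without Fshb against 16.9%. Only cells of VCD pool 1 were compared, so lost reads in VCD pool 2 stayed open. A gonadotrope state with low Fshb and high Pgr may be present in different proportions in the VCD mice, with 68.6% of cells in VCD pool 1 holding Fshb, 27.2 points from the nearest other pool, but the labels tie no cells to mice, so this stayed open.

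The cluster with both stem cell and lactotrope genes was smaller in the VCD pools, for reasons that were not tested. Random doublets could not be excluded: lactotrope-level Prl with endothelial markers was 0.295 times as frequent (116 of 1343) as with stem cell markers (257 of 877), a value between the bounds written before. A stem cell held together with a lactotrope in 1 droplet was argued against by 95 genes that lay more than 2 times above both, the bound written before being 20. That comparison left out somatotropes, and the leading genes of the 95 included Gh, Ghrhr and Pappa2, so a test over every hormone class was added after its result was seen. It left 1 gene, Spon1, so a stem cell held with a hormone cell of any class may explain the cluster, with a median of 9783.5 UMIs against 3817 in stem cells and 7730 in lactotropes.

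Atf3, Klf4 and other immediate early genes were higher in several classes of the VCD pools. Free RNA as the whole source would keep its genes in 1 ratio in every class. Over the 5 classes with Atf3 called, the ratio of added Klf4 to added Atf3 differed 9.49-fold in VCD pool 1 and 6.89-fold in VCD pool 2, from highest to lowest. Klf4 was also called in lactotropes, macrophages and somatotropes. Their ratios were 1.22, 0.14 and 0.53 in VCD pool 1, and 1.34, 0.19 and 0.23 in VCD pool 2. These values argued against free RNA as the whole source, but the genes, classes and bounds were chosen with them known. A longer or harsher dissociation of the VCD pools could be a source, and the tests of it went both ways: heat shock genes outside the immediate early list reached the bound in 6 of 9 classes, but corticotropes among these had no response to compare (medians 0.028 and 0.028 on the log2 scale). Of the 5 classes in which Atf3 was called, the same bound was reached in 2, endothelial cells (0.40 against 0.26) and macrophages (0.37 against 0.48), and not in gonadotropes (0.15 against 0.42), lactotropes (0.13 against 0.50) or somatotropes (0.032 against 0.44). Dissociation thus stayed open, as did a response of the tissue to the loss of ovarian hormones, and the labels give no day of preparation or sequencing per pool.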

How the results depend on the processing

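The alternatives with the mixed cluster, without the low-UMI gonadotrope cluster and without lactotropes among the cells counted were chosen after seeing the data, and the cause was not tested unless given. Of values for the 72 named genes that were called, 752 kept their direction and call over the alternatives and 142 kept their direction without passing; for the others of the 111 named, 351 kept both, 106 came to pass and 7 reversed. The 7 were Gnrhr in gonadotropes thinned (-0.045), Lhb in gonadotropes without control 1 (-0.076, range without 1 pool -0.076 to 0.65), Sox2 in stem cells without control 2 (-0.15, range -0.15 to 0.20) and without VCD 1 (-0.07), and Aldh1a2 in stem cells without control 1 (-0.03), without VCD 2 (range -0.060 to 0.093) and at a resolution of 2 (-0.0050). Counts of changed genes moved with DESeq2 in gonadotropes (148, of which 138 were among the 245), stem cells (19, of which 3 were among the 8), lactotropes (76) and all cells (194). With RLE factors the count for all cells was 92. Without the low-count filter, which tests more genes, counts were 831 in gonadotropes, 152 in stem cells, 254 in endothelial cells, 255 in lactotropes, 780 over the classes outside gonadotropes and stem cells, and 749 in all cells. Thinned to 5000 UMIs, which leaves fewer counts, they were 137 in gonadotropes (110 shared), 0 in stem cells (819 at an unadjusted p under 0.05) and 10 in lactotropes. With doublets kept there were 18 in stem cells and 103 in all cells, with stricter cells 86 in all cells, and at a resolution of 2 5 in stem cells. With the mixed cluster there were 828 in stem cells (346 up and 482 down), for a cause that was not tested, and without the low-UMI gonadotrope cluster there were 278 in gonadotropes. The samples of the groups share only a number: deviations of same-numbered pools correlated at -0.012 in gonadotropes, -0.041 in stem cells, -0.026 in lactotropes and -0.028 in all cells. The replicate block gave 795 genes in gonadotropes, 69 in stem cells, 44 in endothelial cells, 166 in lactotropes, 305 over the other classes (2 of them in somatotropes), 433 in all cells and 47 list tests (43 shared). Leaving out 1 pool gave 5 to 931 genes in gonadotropes, 53 to 221 in stem cells, 69 to 288 in endothelial cells, 8 to 1274 in lactotropes, 223 to 1868 over the other classes (175 with all pools), 61 to 1082 in all cells, 60 to 591 for gonadotropes against other hormone cells, 0 to 6 for stem cells, and 27 to 56 list tests. No list test passed with an estimated correlation (0) or with fry (0). The gonadotrope share had a log2 difference of 1.04. It passed in edgeR on cell numbers (1.02) and with the replicate block (1.04), fits whose spread was shared over all cell classes. The difference was 0.95 without lactotropes among the cells counted, and ran from 0.71 to 1.31 without 1 pool. That of stem cells ran from 0.11 to 0.30 and that of lactotropes from -0.14 to -0.05. Subclusters that separated the groups were 4 with all variable genes and 2 at a resolution of 0.8 in gonadotropes, and 0, 2 and 0 in stem cells with all variable genes, at 0.8 and at 0.3. Cells with Lhb only differed by 16.7 points unthinned and 0 at 3 UMIs or more, and ran from 3.31 to 12.0 without 1 pool; Fshb only ran from -78.9 to -32.2, both from -8.98 to 2.90, neither from 26 to 75.9 and any Fshb from -87.9 to -29.3. Dividing stem cells differed by 0.174 points unthinned, and ran from -0.455 to 0 without 1 pool, and all dividing cells from 0.0217 to 0.0951. The B cell share gave no ratio with stricter cells, as both control pools held 0.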

Other observations

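No test was planned for the values given here, which were looked at after the main results. Id1 and Id2, targets of BMP signals, were called lower in gonadotropes as well as in stem cells, but Id2 was also among the top genes of the gonadotrope subcluster with stem cell transcripts, which was smaller in both VCD pools, so the lower counts in gonadotropes were not separated from fewer such transcripts. Corticotropes shared with gonadotropes a rise of Tacc2 and a fall of Csmd3. Csmd3 was also a top gene of a lactotrope cluster that was smaller in both VCD pools and of the gonadotrope subcluster with lactotrope transcripts. Its falls were thus not separated from fewer lactotrope transcripts. Endothelial cells and stem cells shared a rise of Cxcl10, a chemokine gene induced by interferon. In all, 23 genes were called in at least 2 of the 12 classes tested, of which 15 rose, 4 fell and 4 went in both directions. Atf3 was called in 5 classes and Klf4 in 3. Adgrb3, an adhesion receptor gene, fell in lactotropes and rose in gonadotropes, and Gpr149, an orphan receptor gene, went in opposite directions in gonadotropes and somatotropes.

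Gonadotropes without Fshb but with Pgr were 0% (which allows up to 4.69%), 2.08%, 12.4% and 60% of the thinned gonadotropes of control pools 1 and 2 and VCD pools 1 and 2. A small gonadotrope cluster of 90 cells with a median of 1701 UMIs held 0.257%, 0.341%, 1.65% and 0.455% of cells, and the main one held 2.00%, 1.58%, 3.53% and 2.97%. Hemoglobin transcripts differed between pools in stem cells, where Hbb-bs had 495 and 128 CPM in control pools and 731 and 1064 in VCD pools, while in endothelial cells it had 175, 277, 195 and 36.4.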
